A study of Sus scrofa with 9 samples.

How the data were processed

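Total RNA of 9 porcine samples was hybridised to Affymetrix PorGene 1.0 ST arrays, 1 sample per array: 3 of ESMG, 3 of the overlying squamous tissue and 3 of ESMG-derived spheroids. Per the labels' protocols, tissue RNA was isolated with a Qiagen RNeasy Universal Mini kit and spheroid RNA with an RNeasy Micro kit, and amplified cRNA was turned into single-stranded cDNA, fragmented and labelled with biotin. The series' design text states 3 biological replicates per group and no technical ones. Each sample's group and pig number were taken from its title.

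The deposited values are log2 RMA levels from a gene-level analysis of the full probe set list in Affymetrix Expression Console, per the labels. Transcriptome Analysis Console 3.0 is also named, with no role given, per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays alike and summarises probes into 1 value per probe set, so array-wide differences in RNA amount are removed and differences near the floor are compressed. The version of Expression Console and a genome build are not given in the sources used here. Medians of the deposited arrays were close but not equal (6.84 to 7.04), and no further normalization was applied in the main setting. No detection p-value was used, so a low level is not read as absence. Each of the 9 value columns matched 1 sample, and 0 columns were left unmatched.

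Of 27558 probe sets, the platform annotation gave 13157 exactly 1 gene symbol and 523 several symbols, and did not name 13878. Symbols were updated through the gene number with the RefSeq gene table of the Sus scrofa reference assembly; 12841 of the 13157 probe sets matched, 316 kept the annotation's symbol, and 7 symbols changed. No coordinates are given because no build is named for the array. Where a gene had several probe sets (881 genes), the one with the highest mean over the 9 arrays stood for it, which left 12217 genes, 1139 of them with a locus identifier for a symbol. Among the 881, 36, 193 and 187 genes had at least 1 called probe set in ESMG versus squamous, spheroids versus ESMG and spheroids versus squamous; the probe sets were called in part in 12, 75 and 74 of them and in opposite directions in 0, 0 and 1. The probe sets of named genes that had more than 1 (AQP5, ITGA3, CDK1, GABRP, KCNN4 and VEGFA) were called the same way; the 2 of GABRP held the same values.

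A group-means model was fitted to all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), which left 6 residual degrees of freedom, and 3 comparisons were made: ESMG versus squamous, spheroids versus ESMG and spheroids versus squamous. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. The median standard error of a log2 fold change was 0.17. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

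Before the data were examined, 20 gene lists with 506 symbols were fixed, of which 328 were measured: squamous differentiation, squamous basal layer, mucous and serous secretion, glandular and ductal epithelium, ion and bicarbonate transport, gastric and intestinal columnar, cell cycle, EGF and ERK response, immediate early response, cholesterol synthesis, hypoxia and glycolysis, interferon response, and markers of smooth muscle and myoepithelium, fibroblasts and matrix, endothelium, leukocytes, plasma cells, nerve and glia, adipocytes and skeletal muscle. For each list the called members were counted, and limma's camera with a preset correlation of 0.01 compared the list with the other genes, adjusted over 60 tests. Of these, 32 were called with the preset correlation and 0 with an estimated one. With an estimated correlation, camera also falls back on the 6 residual degrees of freedom, so a lost call is not by itself a sign of correlated genes. In ESMG versus squamous, the ion transport and plasma cell lists had estimated correlations of -0.017 and 0.0011, under the preset. Their adjusted p still rose from 0.000704 to 0.0634 and from 0.0122 to 0.133. The rule for named genes was also fixed before the data were examined: the key genes KRT5, KRT4, KRT7, KRT8, TP63, SOX9, MUC5B, AGR2, MKI67 and VIM where measured; the 4 largest rises and the 4 largest falls per comparison among called genes with a symbol that is not a locus identifier and with arrays that do not overlap between the groups; and the 2 called members with the largest change of each list with at least 3 called members. KRT4, KRT7, TP63, MUC5B, MKI67 and VIM are not analysed here, since no probe set with 1 symbol was matched to them. Other list members are named where few were called and are marked as chosen after their values were seen.

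The position of the spheroids was described over the genes called between ESMG and squamous tissue. Genes on which spheroids differ from both tissues were counted beside the overlap of independent lists and 20 simulations of unchanged groups. The ESMG and squamous arrays of pigs 37, 39 and 40 come from the same animals, so the pig numbers of the titles pair them. Deviations from the group means, across genes, correlated at 0.42 within pig 37, -0.15 within pig 39 and -0.17 within pig 40, and the consensus correlation within a pig was -0.15. The stated design has no pairing, so the pig entered only as an alternative, as a random block in the fit of the 9 arrays or a fixed block in that of the 6 tissue arrays. Camera takes no random block, and the lists of that alternative were tested with cameraPR on the moderated statistics.

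The code was tested on simulated data of 12217 genes with 200 changed. For ESMG versus squamous, 95% of genes changed by 1.5 on the log2 scale and 98% of those changed by 3 were called; for spheroids versus ESMG 93% and 99%; for spheroids versus squamous 96% and 100%. Unchanged genes called numbered 1, 0 and 4, and 0, 1 and 2 of 50 random lists had a camera p under 0.05. The simulated genes were drawn independently of each other, whereas the estimated correlation of the leukocyte list was 0.69. The simulation therefore does not give the error rate of the list test for the fixed lists. The alternatives were quantile normalization again, equal array medians, cyclic loess, leaving out the dimmest 1 in 3 genes, other rules for several probe sets, other variance models, array weights, fits of only the arrays compared, other thresholds, limma's treat, the pig blocks, other list tests and leaving out each array in turn.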

Results

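Gene expression was measured in pig esophagus on 9 Affymetrix PorGene 1.0 ST arrays, each hybridised with total RNA of a single sample. Of these, 3 arrays held esophageal submucosal glands (ESMG), the mucus- and fluid-secreting glands that lie under the esophageal lining. Another 3 held the squamous tissue that overlies the glands, taken from the same 3 animals (pigs 37, 39 and 40). The last 3 held spheroids grown in vitro from ESMG and labelled pig 1, 2 and 3; how these animals relate to pigs 37, 39 and 40 is not given in the sources used here. The spheroids were cultured in Matrigel under Advanced DMEM/F12 medium with B27 and N2 supplements, 10 mM HEPES and 50 ng/ml of human epidermal growth factor (EGF). Values are log2 RMA levels, so a difference of 1 is a 2-fold difference. The median level over all probe sets lay between 6.84 and 7.04 on every array, and 12217 genes with a named probe set were tested. For arrays, precision is limited by their number, which was 3 per group.

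The spheroids stood apart from both tissues. The first principal component held 67.5% of the variance and put the 3 spheroid arrays between 63.3 and 64.1, and the 6 tissue arrays between -34.9 and -28.5. The second component, with 16.7%, separated ESMG from squamous tissue. On it the ESMG arrays of pigs 37 and 39 lay at 34.7 and 34.7 and the squamous arrays between -34.1 and -18.3, while the ESMG array of pig 40 lay at 6.09, between the tissues. Correlations across genes, which are not independent replicates, were 0.976 to 0.985 among ESMG arrays, 0.980 to 0.987 among squamous arrays and 0.983 to 0.990 among spheroid arrays. Between spheroids and ESMG they were 0.877 to 0.897, and between spheroids and squamous tissue 0.880 to 0.893. No 2 arrays held identical values.

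**Figure D1:**
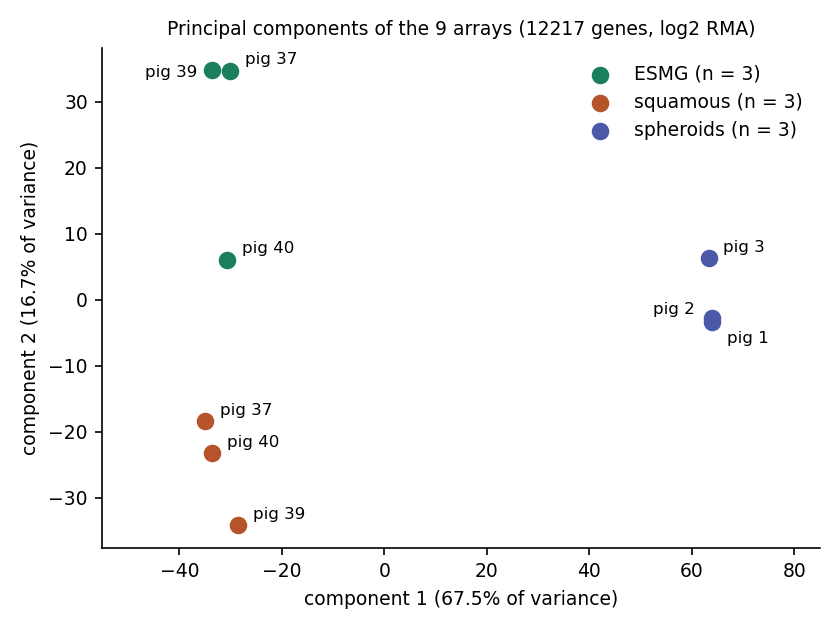
Principal components of the 9 arrays over 12217 genes; the axes are scores on component 1 (67.5% of the variance) and component 2 (16.7%), and each point is an array coloured by group and marked with its pig. The spheroid arrays lie at 63.3 to 64.1 on component 1, and the ESMG array of pig 40 lies at 6.09 on component 2, between the other ESMG arrays and the squamous arrays.

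The first comparison asked which genes distinguish the glands from the lining above them. Among the tested genes, those of mucous secretion led the difference. AGR2, an endoplasmic reticulum protein needed for mucin folding, was 66.0-fold higher in ESMG, at 12.56 ± 0.37 against 6.51 ± 1.57 (SD, n = 3 each; log2 difference 6.05 with SE 0.57, adjusted p = 0.000106). CLCA1, a secreted protein of mucous cells, was 62.3-fold higher, MUC19, a gel-forming mucin, 49.2-fold and the secretoglobin SCGB1D1 39.9-fold. Over the settings run the log2 difference ranged from 5.06 to 6.93 for AGR2, from 4.87 to 6.92 for CLCA1 and from 4.56 to 6.08 for SCGB1D1, with the highest of each without the squamous array of pig 37. In all, 374 genes were called, 324 of them higher in ESMG and 50 higher in squamous tissue. The falls were smaller than the rises: HPSE2, a heparanase relative without its enzyme activity, was 4.01-fold lower in ESMG (-2.00, SE 0.23, adjusted p = 0.000426), and PYGM, the glycogen phosphorylase of muscle, PRUNE2 and CASQ2, a calcium-binding protein of muscle, were 3.53-fold, 3.41-fold and 3.32-fold lower.

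Of 18 measured genes of mucous and serous secretion, 11 were higher in ESMG and none lower, with a median log2 difference of 1.83 (camera adjusted p = 1.98e-20; adjusted p = 0.0634 with an estimated correlation). Of 16 glandular and ductal genes, 7 were higher and none lower (adjusted p = 2.45e-08; adjusted p = 0.0634 with an estimated correlation). They included the keratins of simple epithelium KRT18, 9.75-fold higher (log2 3.29, SE 0.25), and KRT8, 7.27-fold higher (log2 2.86, SE 0.25, adjusted p = 7.36e-05), and the progenitor transcription factor SOX9, 2.96-fold higher (log2 1.56, SE 0.27, adjusted p = 0.00578). Of 19 genes of ion and bicarbonate transport, 7 were higher and 1 lower (adjusted p = 0.000704; adjusted p = 0.0634 with an estimated correlation). The sodium-potassium-chloride cotransporter SLC12A2 was 9.54-fold and the water channel AQP5 4.91-fold higher, and the lower gene, picked out after its value was seen, was the proton pump subunit ATP6V1B1 at -1.03. The median of that list was 0.07 and ranged from 0.04 to 0.21 over the settings run. Of 21 gastric and intestinal columnar genes, 3 were higher, among them OLFM4, a secreted marker of intestinal crypts, 7.08-fold (log2 2.82, SE 0.60, adjusted p = 0.0169), and the transcription factor FOXA1, 4.37-fold. That list as a whole was not called (adjusted p = 0.762), its median of -0.15 (from -0.24 to 0.45 over the settings run) and mean of 0.23 differing in sign.

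No measured squamous gene of the fixed lists was called. Of 31 squamous differentiation and 22 basal-layer symbols, 17 and 11 were measured, and KRT13, IVL and KRT14 were among those that were not. None of 17 squamous differentiation genes and none of 11 basal-layer genes reached a call, and the list medians were -0.48 (camera adjusted p = 1.69e-06; adjusted p = 0.265 with an estimated correlation) and -0.37 (adjusted p = 0.00131; adjusted p = 0.209 with an estimated correlation). KRT5, the keratin of basal squamous cells, was 12.85 ± 0.38 in ESMG and 13.29 ± 0.13 in squamous tissue (SD, n = 3 each; log2 difference -0.44, SE 0.18, adjusted p = 0.215). Smooth muscle and myoepithelial genes fell in 3 of 16 (median -0.78, camera adjusted p = 2.44e-08; adjusted p = 0.141 with an estimated correlation), among them the calcium pump regulator PLN at -1.38 and the actin-binding SYNPO2 at -1.29.

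Among markers of blood cells, 1 of 21 leukocyte genes was higher, LCP1 at 1.24, with a list median of 0.60 (camera adjusted p = 2.78e-06; adjusted p = 0.415 with an estimated correlation). That median was 0.16 without the ESMG array of pig 37 and 0.86 without that of pig 39, and under fry, which tests whether a list's genes move one way, the list was not called (adjusted p = 0.206). Of 9 plasma cell genes 2 were higher, JCHAIN, the joining chain of secreted antibodies, at 4.47 and DERL3 at 1.49 (adjusted p = 0.0122; adjusted p = 0.133 with an estimated correlation). These 3 genes were named after their values were seen. No cell cycle gene of 21 was called, and that list had a median of -0.28 (adjusted p = 0.0180; adjusted p = 0.464 with an estimated correlation). Of 21 EGF and ERK response genes 2 were higher, PHLDA1 at 1.16 and CXCL8 at 3.33, both picked out after their values were seen, and 1 of 17 skeletal muscle genes was lower, the PYGM named above. Those 2 lists, and those of immediate early response, cholesterol synthesis, hypoxia, interferon response, fibroblasts, endothelium, nerve and adipocytes, in which no gene was called, were not called (adjusted p from 0.0543 to 0.974). The cholesterol list was called after quantile normalization (0.0335), cyclic loess (0.0174), without the squamous array of pig 39 (0.0484) and under fry (0.0145). The EGF and ERK, interferon and skeletal muscle lists were each called by camera without some single array (0.00259 to 0.0166). With pig as a fixed block the immediate early list was called (adjusted p = 0.0354 over the 20 lists of that fit, against 0.231 over 60 tests without the block and 0.813 with an estimated correlation). It was also called without the ESMG array of pig 37 (camera adjusted p = 0.0252) or 39 (0.0171), so its call was not particular to the block. The fibroblast list had a median of -0.12 (from -0.16 to 0.10 over the settings run) and a mean of 0.07. Adjusted over the list alone, 12 mucous and serous genes and 1 fibroblast gene were higher, and 4 smooth muscle genes were lower.

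These calls came from limma on 3 arrays per group, and the count depended on the ESMG array of pig 40: without it 569 genes were called, 122 of them lower in ESMG. The lower count was 24 and 25 without the ESMG arrays of pigs 39 and 37, and 30 and 27 without the squamous arrays of pigs 37 and 40; in such fits calls on CASQ2, PYGM, PRUNE2 and OLFM4 were lost. PYGM lost its call without the ESMG array of pig 37 or any single squamous array (adjusted p from 0.0545 to 0.112), with pig as a random block (adjusted p = 0.0583) and in the fit of the 6 tissue arrays alone (adjusted p = 0.0695). The log2 difference of PYGM was -1.23 and that of OLFM4 3.41 without the ESMG array of pig 39, and that of OLFM4 was 1.94 without that of pig 37. CASQ2 lost it without either array of pig 37, the ESMG array of pig 39 or the squamous array of pig 40 (0.0608 to 0.0905). PRUNE2 lost it without the squamous array of pig 40 (adjusted p = 0.0619), and OLFM4 without that of pig 39 (adjusted p = 0.0595) or 40 (adjusted p = 0.0722). The cell cycle and plasma cell list calls ended without the ESMG array of pig 40, and that of the cell cycle list also without the squamous array of pig 40 and under fry (adjusted p = 0.141). The plasma cell call also ended with the dimmest 1 in 3 genes left out (adjusted p = 0.130), and over the settings the median of that list ranged from 0.11 to 0.31 and that of the cell cycle list from -0.32 to -0.11.

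**Figure D2:**
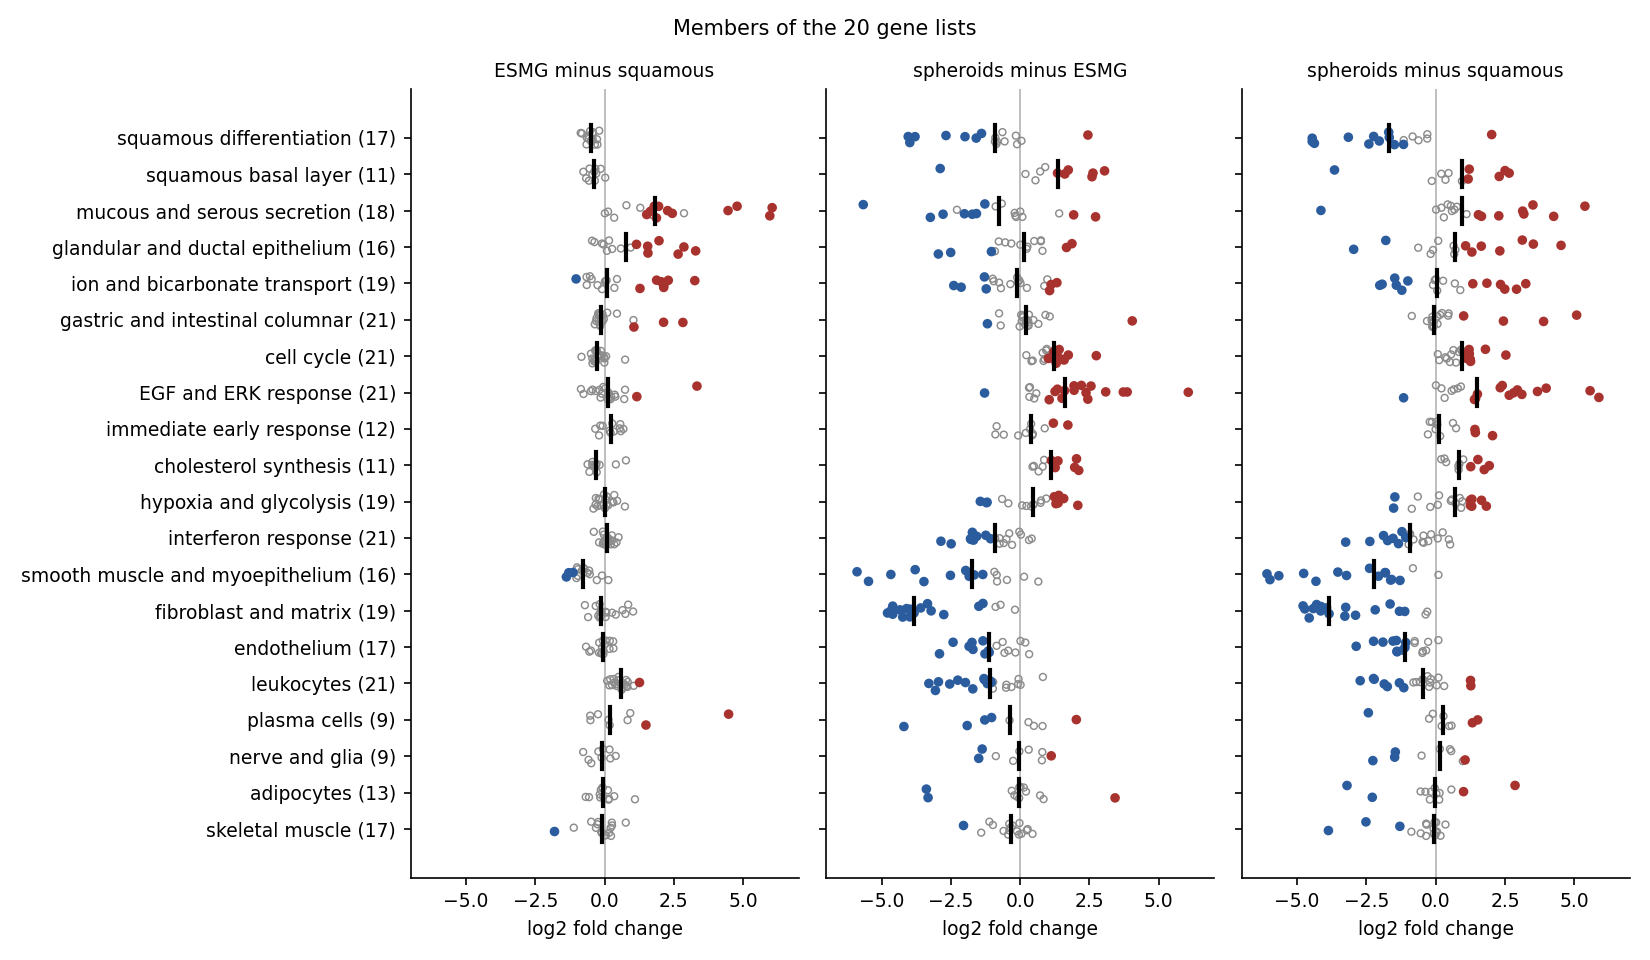
Log2 fold changes of the measured members of 20 gene lists in the 3 comparisons; each point is a gene (filled red, called higher; filled blue, called lower; open, not called), the black bar is the list median, and the number of measured genes stands in parentheses. Secretory genes lie to the right in ESMG against squamous tissue (median 1.83), and fibroblast genes to the left in spheroids against either tissue (medians -3.83 and -3.85).

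The comparison of spheroids with ESMG asked how spheroids differ from gland tissue. By count of called genes, the fibroblast (16 of 19), smooth muscle (10 of 16), leukocyte (12 of 21) and endothelial (9 of 17) lists had most members lower in spheroids, and the EGF and ERK (15 of 21), cell cycle (13 of 21), cholesterol (6 of 11) and basal-layer (6 of 11) lists had most members higher. Every list call of this comparison was lost with an estimated correlation (adjusted p from 0.0634 to 0.425 with an estimated correlation). A total of 2065 genes were called, 976 higher and 1089 lower in spheroids; the split was 1244 and 935 with array medians set equal and 755 and 1245 after cyclic loess. The largest rises were in PLET1, a surface protein of epithelial progenitors (209-fold; 12.16 ± 0.37 against 4.45 ± 0.62, SD, n = 3 each; log2 difference 7.71, SE 0.28, adjusted p = 1.38e-08), AREG, a ligand of the EGF receptor (66.9-fold), the collagenase MMP13 (57.2-fold) and BNC1, a zinc finger protein of basal keratinocytes (19.8-fold). The largest falls were in PHEROC, a salivary pheromone-binding protein (193-fold lower; log2 difference -7.59, SE 0.74, adjusted p = 1.12e-05), SCGB1D1 (142-fold), MGP, a matrix protein that inhibits calcification (129-fold), and MUC19 (60.4-fold). The log2 difference of SCGB1D1 ranged from -7.83 to -6.77 over the settings run. No detection call was used. The lower level of PLET1, AREG, PHEROC, SCGB1D1, MGP, CA6, SCN7A and CD36 in this comparison lay under the lower quartile of every array (5.36 to 5.65), so their folds depend on RMA values near the floor. That of MMP13, at 5.40 in ESMG, lay under the lower quartile of each ESMG array (5.51 to 5.59).

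Key epithelial genes moved less. KRT5 was 1.87-fold higher in spheroids (log2 0.90, SE 0.18, adjusted p = 0.00185), under the 2-fold minimum, and passed it without the ESMG array of pig 40 (log2 1.04), with arrays set to equal medians (1.02) and with array weights (1.11). KRT8 was at 11.47 ± 0.27 in spheroids and 11.20 ± 0.42 in ESMG (SD, n = 3 each; adjusted p = 0.453). SOX9 had a log2 difference of 0.75 (SE 0.27, adjusted p = 0.0461), under the fold minimum, and AGR2 one of -0.66 (SE 0.57, adjusted p = 0.391).

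Of 17 squamous differentiation genes, 7 fell and 1 rose (median -0.90, camera adjusted p = 2.29e-06; adjusted p = 0.265 with an estimated correlation). Cornulin (CRNN), a protein of the upper squamous layers, was 16.4-fold and the protease inhibitor A2ML1 15.8-fold lower. In ESMG these 2 genes lay at 12.27 and 12.80, near their squamous levels of 12.69 and 13.28. Which cells of the ESMG samples gave these levels was not tested, so the falls are not shown to be changes within gland cells. The gene that rose, ALOX12 at 2.44, was picked out after its value was seen. Basal-layer genes went the other way: 6 of 11 rose and 1 fell (median 1.35, adjusted p = 0.000256; adjusted p = 0.161 with an estimated correlation). The laminin receptor subunit ITGA3 was 8.26-fold higher, and the gene that fell was the keratin KRT15, 7.39-fold lower. Among mucous and serous genes 7 of 18 fell and 2 rose (median -0.77, adjusted p = 0.0122; adjusted p = 0.425 with an estimated correlation). Lactoperoxidase (LPO), an antibacterial enzyme of serous cells, was 50.6-fold lower and PIGR, which carries antibodies across epithelium, 9.45-fold lower, whereas the membrane mucins MUC1 (2.72) and MUC20 (1.93) were the 2 that rose, named after their values were seen.

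Glandular and ductal genes split, with 2 of 16 higher and 3 lower; the receptor KIT was 7.74-fold and the transcription factor ELF5 5.68-fold lower, and KRT19 (1.87) and CLDN4 (1.67), picked out afterwards, were higher. Ion transport genes split as well, with 3 of 19 higher and 4 lower: AQP5 was 5.26-fold and the secreted carbonic anhydrase CA6 4.37-fold lower. Of 21 gastric and intestinal columnar genes 1 was higher, MUC13 at 4.04, and 1 lower, GKN2 at -1.18, both named after their values were seen. None of these 3 lists was called by camera (adjusted p = 0.626, 0.182 and 0.497), and the glandular list had a median of 0.12 (from -0.02 to 0.24 over the settings run) and a mean of -0.14. Under fry the ion transport list was called (adjusted p = 0.00413).

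Cell cycle genes rose in 13 of 21 and fell in none (median 1.21, camera adjusted p = 1.35e-07; adjusted p = 0.161 with an estimated correlation), led by the mitotic ubiquitin-conjugating enzyme UBE2C (6.71-fold) and the kinase CDK1 (3.33-fold). EGF and ERK response genes rose in 15 of 21 and fell in 1, SPRY1 at -1.28, named after its value was seen (median 1.60, adjusted p = 4.28e-07; adjusted p = 0.0653 with an estimated correlation). AREG and the urokinase PLAU (14.5-fold) led them. Genes of cholesterol synthesis and uptake rose in 6 of 11 and fell in none (median 1.13, adjusted p = 1.02e-05; adjusted p = 0.0634 with an estimated correlation), with the sterol carrier STARD4 4.33-fold and the mevalonate kinase MVK 4.09-fold higher. Of 19 hypoxia and glycolysis genes 6 rose, among them NDRG1 (4.23-fold) and the glycolytic enolase ENO1 (2.97-fold), and 3 fell. That list was not called by camera (adjusted p = 0.0947) but was called under fry (adjusted p = 0.00113). Interferon response genes fell in 9 of 21 and rose in none (median -0.91, adjusted p = 1.92e-05; adjusted p = 0.406 with an estimated correlation), led by OASL (7.25-fold lower) and IFI44 (5.62-fold lower). Of 12 immediate early genes 2 rose, ATF3 at 1.20 and CYR61 at 1.72, named after their values were seen, and the list was not called (adjusted p = 0.610).

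Fibroblast, smooth muscle, endothelial and leukocyte markers fell beside these groups. Of 19 fibroblast and matrix genes 16 fell and none rose (median -3.83, camera adjusted p = 5.33e-16; adjusted p = 0.0634 with an estimated correlation), among them dermatopontin (DPT, 27.6-fold) and the collagen COL1A2 (25.5-fold). Smooth muscle and myoepithelial genes fell in 10 of 16 (median -1.75, adjusted p = 2.44e-08; adjusted p = 0.141 with an estimated correlation), with the smooth muscle actins ACTA2 59.1-fold and ACTG2 44.4-fold lower. Endothelial genes fell in 9 of 17 (median -1.12, adjusted p = 1.38e-06; adjusted p = 0.0653 with an estimated correlation), such as CD34 (7.52-fold) and PECAM1 (5.35-fold). Leukocyte genes fell in 12 of 21 (median -1.07, adjusted p = 1.10e-05; adjusted p = 0.425 with an estimated correlation), such as CD53 (9.81-fold) and MPEG1 (8.32-fold); the leukocyte median was -0.60 without the ESMG array of pig 37 and -1.84 with the dimmest 1 in 3 genes left out. None of the genes in those 4 lists rose. Plasma cell genes fell in 4 of 9, with JCHAIN 18.3-fold lower, and 1 rose, the epithelial and plasma cell proteoglycan SDC1 (4.07-fold). Of 9 nerve and glia genes 2 fell, SCN7A (2.82-fold) and NCAM1 (2.59-fold), and 1 rose, UCHL1 at 1.12, named after its value was seen. Of 13 adipocyte genes 2 fell, including CD36 (10.4-fold), and 1 rose, ADIRF (10.7-fold). In the skeletal muscle list 1 of 17 fell, PYGM at -2.05, named here after its value was seen. Those last 4 lists were not called by camera (adjusted p from 0.0965 to 0.726). The plasma cell list was called under fry (adjusted p = 0.0163), and the skeletal muscle list by camera without the ESMG array of pig 39 (adjusted p = 0.00315). Counts adjusted over the list alone were equal to those over all genes in each of the 20 lists of this comparison. Tissue and spheroid RNA came from different kits, so culture and RNA isolation changed together.

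**Figure D3:**
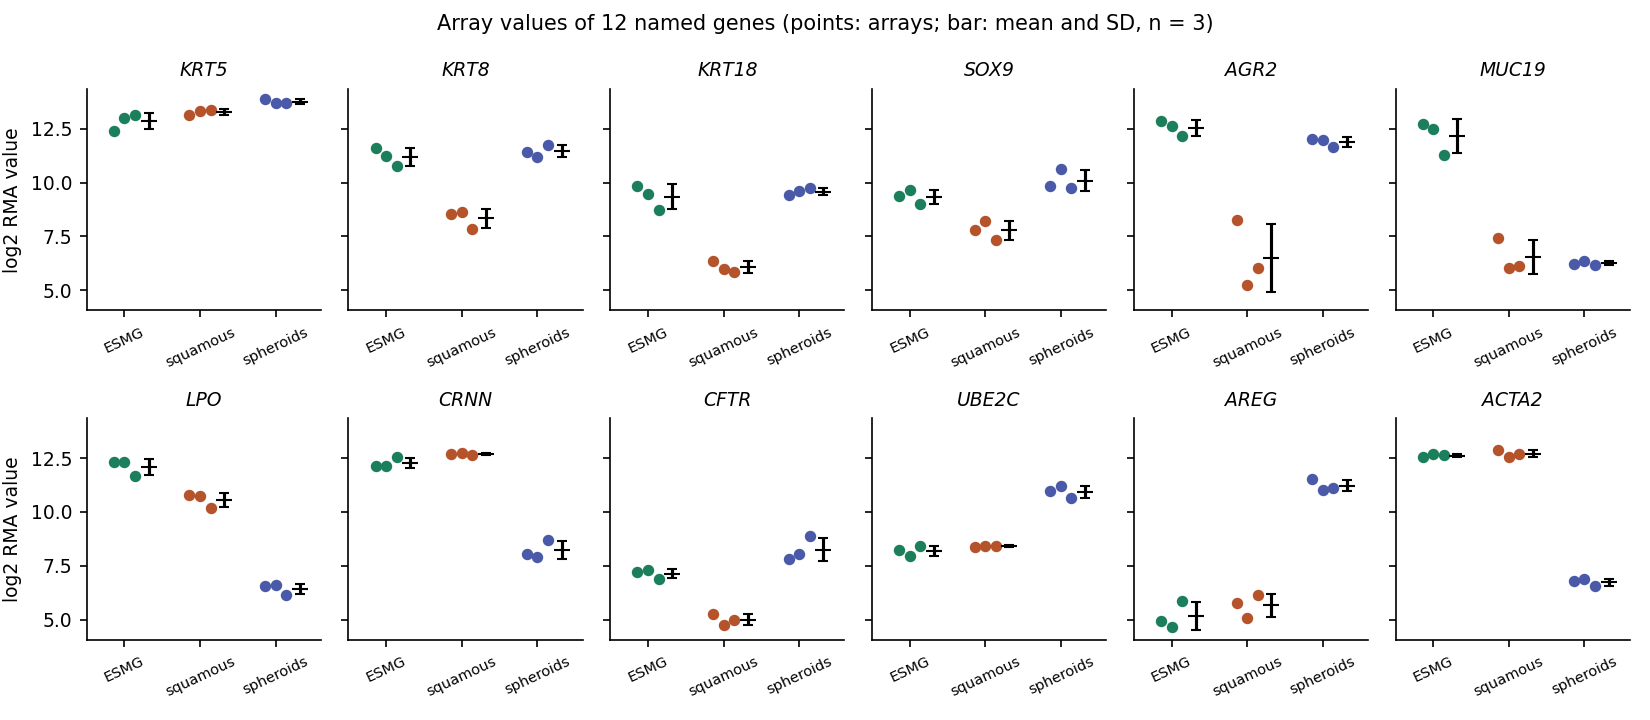
Log2 RMA levels of 12 genes in the 3 groups; each point is an array, and the black bar and whiskers beside it are the mean and SD (n = 3). KRT8, KRT18 and AGR2 were not called between spheroids and ESMG, whereas MUC19 was 60.4-fold and LPO 50.6-fold lower in spheroids.

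Against the squamous tissue, AGR2, KRT8 and SOX9 were higher in spheroids. AGR2 was 41.7-fold higher in spheroids (log2 5.38, SE 0.57, adjusted p = 1.86e-05), KRT8 8.71-fold (log2 3.12, SE 0.25, adjusted p = 2.57e-06) and SOX9 4.97-fold (log2 2.31, SE 0.27, adjusted p = 4.31e-05), while KRT5 was 13.75 ± 0.11 against 13.29 ± 0.13 (SD, n = 3 each; adjusted p = 0.0622). A total of 2035 genes were called, 1052 higher and 983 lower in spheroids. The largest rises were in PLET1 (283-fold; log2 8.14, SE 0.28, adjusted p = 6.30e-09), MMP13 (97.9-fold), GABRP, a subunit of a GABA receptor (63.0-fold), and the neutrophil-attracting chemokine CXCL8 (59.2-fold). Over the settings run the log2 difference of AGR2 ranged from 4.40 to 6.26, that of GABRP from 5.01 to 6.61 and that of CXCL8 from 5.25 to 6.41. The largest falls were in PGM5, a muscle protein of the phosphoglucomutase family (114-fold lower; log2 -6.83, SE 0.30, adjusted p = 2.66e-08), the matrix protein SPARCL1 (81.4-fold), C2H5orf46 (76.9-fold) and MGP (75.9-fold). With array medians set equal, 1370 genes were higher and 834 lower, and after cyclic loess 891 and 1060. The lower level of PLET1, MMP13, PGM5, MGP, CFTR, MUC13, SCN7A and LPL in this comparison lay under the lower quartile of every array (5.36 to 5.65). OLFM4 in squamous tissue, at 5.48, lay under the lower quartile of each squamous array (5.53 to 5.65), which also bears on its fold between the tissues.

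Squamous differentiation genes fell in 11 of 17 and rose in 1 (median -1.68, camera adjusted p = 1.25e-08; adjusted p = 0.179 with an estimated correlation), with A2ML1 22.0-fold and CRNN 21.9-fold lower and ALOX12 again the one that rose, at 2.02. Basal-layer genes rose in 5 of 11 and fell in 1 (median 0.94, adjusted p = 0.00713; adjusted p = 0.273 with an estimated correlation): the laminin chain LAMB3 was 6.28-fold higher and KRT15 12.6-fold lower. Mucous and serous genes rose in 8 of 18 and fell in 1, LPO at -4.14 (median 0.94, adjusted p = 0.00237; adjusted p = 0.385 with an estimated correlation). That median was 1.64 without the squamous array of pig 37. The secreted protease inhibitor WFDC2 was 19.1-fold higher (log2 4.26, from 3.26 to 4.91 over the settings run). Of 16 glandular and ductal genes 7 rose and 2 fell, with no call on the list (adjusted p = 0.0543; adjusted p = 0.406 with an estimated correlation) except with pig as a random block (adjusted p = 0.0258), under fry (adjusted p = 0.000918), or without the spheroid array of pig 1 or 2 or either tissue array of pig 37 (adjusted p from 0.0275 to 0.0477); KRT19 was 23.0-fold and KRT18 11.5-fold higher, and the falls were in ELF5 (-2.96) and KIT (-1.80). Ion transport genes rose in 6 of 19 and fell in 6 (camera adjusted p = 0.633, against 0.0027 under fry), with the chloride channel CFTR 9.51-fold and the potassium channel KCNN4 7.54-fold higher. Of 21 gastric and intestinal columnar genes 4 rose and none fell, among them the membrane mucin MUC13 (33.9-fold) and OLFM4 (14.8-fold). The list was not called (adjusted p = 0.607), with a median of -0.07 (from -0.10 to 0.11 over the settings run) and a mean of 0.56. ALOX12, LPO, ELF5 and KIT were named in this comparison after their values were seen.

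Cell cycle genes rose in 9 of 21 and fell in none (median 0.96, camera adjusted p = 3.62e-06; adjusted p = 0.210 with an estimated correlation), again led by UBE2C (5.78-fold) and CDK1 (3.47-fold). EGF and ERK response genes rose in 13 of 21 and fell in 1, SPRY1 at -1.16, named after its value was seen (median 1.50, adjusted p = 1.32e-07; adjusted p = 0.0634 with an estimated correlation), with CXCL8 and AREG (47.5-fold) highest. Of 11 cholesterol genes 4 rose and none fell (median 0.85, adjusted p = 8.28e-05; adjusted p = 0.0664 with an estimated correlation), STARD4 by 3.82-fold and MVK by 3.36-fold. Of 12 immediate early genes 3 rose, including CYR61 (4.14-fold) and NR4A2 (2.69-fold), with no call on the list (adjusted p = 0.329). Hypoxia and glycolysis genes rose in 6 of 19, such as NDRG1 (3.54-fold) and VEGFA (3.14-fold), and fell in 2 (median 0.71, camera adjusted p = 0.0429, and 0.385 with an estimated correlation). That call was lost under each of the 3 rescalings, with the dimmest 1 in 3 genes left out (adjusted p = 0.2005) and, among single arrays, without the squamous array of pig 37 or the spheroid array of pig 3. The list median lay between 0.72 and 0.84 under the 3 rescalings and without the dimmest genes. Interferon response genes fell in 8 of 21 and rose in none (median -0.92, adjusted p = 0.000194; adjusted p = 0.425 with an estimated correlation), with OASL 9.50-fold and IFI44 5.19-fold lower (log2 -2.38, from -2.99 to -2.03 over the settings run).

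Fibroblast, smooth muscle and endothelial markers were again lower. Fibroblast and matrix genes fell in 17 of 19 (median -3.85, camera adjusted p = 1.65e-15; adjusted p = 0.0634 with an estimated correlation), with COL1A2 27.6-fold and COL3A1 26.4-fold lower. Smooth muscle genes fell in 14 of 16 (median -2.23, adjusted p = 1.53e-12; adjusted p = 0.0734 with an estimated correlation), with ACTG2 68.1-fold and ACTA2 63.2-fold lower. Endothelial genes fell in 10 of 17 (median -1.11, adjusted p = 1.35e-07; adjusted p = 0.0634 with an estimated correlation), with CD34 7.31-fold and PECAM1 4.74-fold lower. In those 3 lists no gene rose. Leukocyte genes fell in 7 of 21, MPEG1 by 6.61-fold and CD53 by 4.74-fold, and rose in 2, LCP1 at 1.26 and AIF1 at 1.27, named after their values were seen (median -0.48, adjusted p = 0.0125; adjusted p = 0.728 with an estimated correlation). The leukocyte median was -0.29 after quantile normalization and -1.23 with the dimmest 1 in 3 genes left out, and under fry that list was not called (adjusted p = 0.164). With pig as a random block the leukocyte and hypoxia lists were not called (adjusted p = 0.0554 and 0.0731). Of 9 plasma cell genes 2 rose, including SDC1 (2.86-fold), and PRDM1 fell (5.39-fold). Of 9 nerve and glia genes 3 fell, including SCN7A (4.82-fold) and NCAM1 (2.79-fold), and 1 rose; the list had a median of 0.15 and a mean of -0.27, and its median ranged from -0.67, with the dimmest 1 in 3 genes left out, to 0.28. Of 13 adipocyte genes 2 fell, including LPL (9.19-fold), and 2 rose, including ADIRF (7.27-fold). Skeletal muscle genes fell in 3 of 17, including PYGM (14.6-fold) and ACTN2 (5.73-fold). Those last 4 lists were not called by camera (adjusted p from 0.0877 to 0.644). The nerve list was called under fry (adjusted p = 0.0374), and the skeletal muscle list by camera without the ESMG array of pig 37 (adjusted p = 0.0475) or 39 (0.0412). Adjusted over the list alone, 12 squamous differentiation genes were lower; counts in the other lists were equal to those over all genes.

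The next comparison asked on which side of the tissue contrast the spheroids lay, over the genes called between ESMG and squamous tissue. Their fold and direction come from the tissue means, while the spheroid arrays entered the pooled spread; the 6 tissue arrays alone gave 335 genes. Part of the genes higher in ESMG stayed above squamous tissue in spheroids, and others did not. Of the 324 genes higher in ESMG, 81 were not called against ESMG and were higher in spheroids than in squamous tissue, whereas 131 were lower in spheroids than in ESMG and not called against squamous tissue. Of the 11 mucous and serous genes among them, 7 were lower in spheroids than in ESMG, including CLCA1, PIGR and LPO; 4 were not called, including AGR2 and WFDC2. Of the 7 glandular and ductal genes, only KIT was lower in spheroids than in ESMG, and KRT8, KRT18, KRT19 and SOX9 were among 5 that were higher than in squamous tissue. Of the 7 ion transport genes, 2 were lower than in ESMG, AQP5 and CA6, and 5 were higher than in squamous tissue, including CFTR, KCNN4 and SLC12A2. A missed call does not show equal levels. Only 33 of the 324 genes were in any fixed list, and JCHAIN and DERL3 of the plasma cell list were among the 131. Fibroblast (16 of 19), leukocyte (12 of 21) and endothelial (9 of 17) genes also fell in spheroids against ESMG. The 131 can therefore include genes of cell types that were fewer in culture, which was not tested.

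By distance, the spheroid mean lay nearer the squamous mean for 192 of the 324 genes (59.3%) and nearer the ESMG mean for 132. It lay between the tissue means for 161 genes, below the squamous mean for 98 and above the ESMG mean for 65. Nearness therefore does not mean a level like that of the nearer tissue. On the single spheroid arrays of pigs 1, 2 and 3 the squamous share was 60.5%, 59.6% and 54.3%. Of the 50 genes higher in squamous tissue, 7 (14%) lay nearer the squamous mean, and 39 lay beyond the ESMG mean, that is, still lower. Of these 50, 3 were in the smooth muscle list (PLN, SYNPO2 and KCNMB1), 1 was PYGM of the skeletal muscle list, and 0 were in the squamous differentiation or basal lists; smooth muscle genes fell in spheroids against squamous tissue in 14 of 16. KCNMB1 was named after its value was seen. Without the ESMG array of pig 40 the share was 20.5% of the squamous-higher genes, and without that of pig 39 it was 4.17%. These shares are descriptions, since 3 arrays against 3 cannot reach p under 0.05 in an exact permutation test. Over all 12217 genes the mean Euclidean distance of the spheroid arrays was 103.9 to ESMG and 104.2 to squamous arrays, a difference of -0.31 that turned to 1.38 without the ESMG array of pig 40, to 0.10 without the squamous array of pig 40, to 0.47 without the spheroid array of pig 3 and to 0.46 after cyclic loess.

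**Figure D4:**
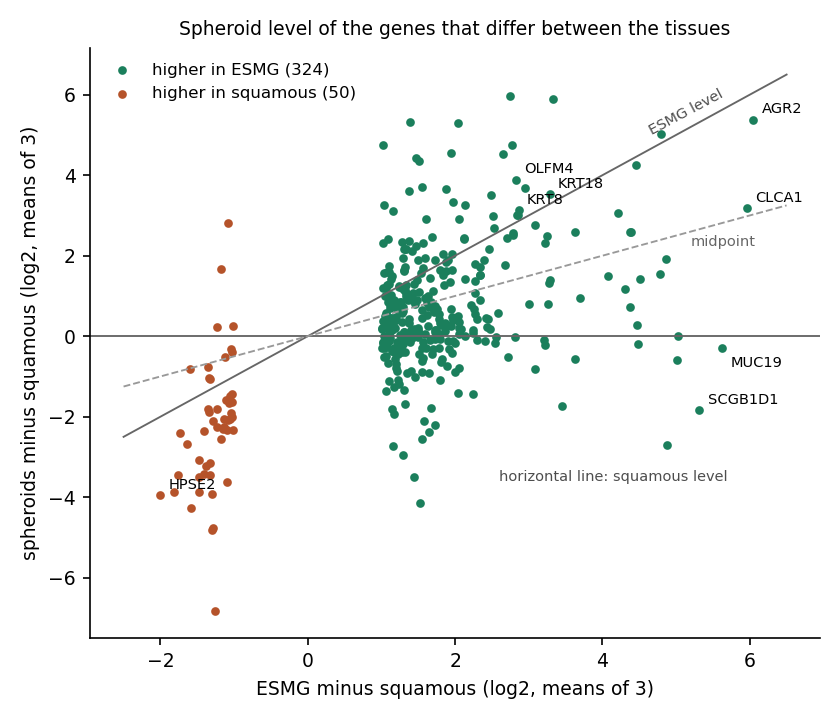
Spheroid level against tissue difference for the 374 genes called between the tissues; the x axis is the ESMG mean minus the squamous mean and the y axis the spheroid mean minus the squamous mean (log2, means of 3 arrays), with solid lines at the ESMG and squamous levels and a dashed line at the midpoint. Of 324 genes higher in ESMG, 192 lie nearer the squamous level, 98 of these below it, and of 50 higher in squamous tissue, 39 lie beyond the ESMG level.

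Most spheroid differences held against both tissues. Higher than in both were 748 genes, among them PLET1, MMP13, AREG, UBE2C, MVK and LAMB3, and lower than in both were 742, among them MGP, ACTA2, COL1A2, CRNN, OASL and KRT15. Another 13 genes were called in opposite directions. Independent lists of these sizes would share 84.0 higher and 87.6 lower genes, and simulated unchanged groups that share the spheroid arrays shared 0 on average in 20 simulations; with so few unchanged genes called at all, this 0 does not measure what the shared arrays add to the overlap. The log2 fold changes of the comparisons correlated at 0.86 across genes, against 0.50 in the simulation, and their covariance was 0.69 against 0.022, a difference of 0.67. Part of the excess of shared genes over independent lists may come from the shared spheroid arrays, which were too few to split; the simulated covariance already holds their share, so the covariance difference leaves it out.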

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

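The tests of the RNA kit and of exchanged labels were chosen only after the result was seen. Probe sets without exactly 1 gene symbol were outside the comparisons, and many of the 14401 passed the same thresholds. They numbered 195 in ESMG versus squamous tissue (175 higher and 20 lower), 1915 in spheroids versus ESMG (741 higher and 1174 lower) and 1924 in spheroids versus squamous tissue (749 higher and 1175 lower). The median of their mean levels was 6.56, against 7.44 for the tested genes. In ESMG versus squamous tissue their largest log2 rise was 6.33 and their largest fall -2.58, against 6.05 and -2.00 for the tested genes.

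Cell cycle, EGF and ERK, and cholesterol genes rose in spheroids against ESMG (adjusted p = 0.161, 0.0653 and 0.0634 with an estimated correlation) while fibroblast and leukocyte markers fell (adjusted p = 0.0634 and 0.425 with an estimated correlation), and a candidate explanation is a higher share of epithelial cells. A list of 30 epithelial genes written before its values were seen had a median log2 change of 0.38 over 17 measured members. The cell cycle median exceeded it by 0.83 (95% bootstrap interval over genes 0.43 to 1.10), that of EGF and ERK by 1.22 (0.54 to 2.14) and that of cholesterol by 0.74 (0.23 to 1.58). This argues against a higher share of epithelial cells of all kinds as the whole cause. The intervals treat genes as independent and hold no spread between animals. The epithelial list did not separate ESMG from squamous tissue (median -0.24, 0 called), so a changed share of 1 kind of epithelium stays open. RNA isolation cannot be told apart from culture, because the number of spheroid arrays prepared with the tissue kit was 0. Growth in a medium with 50 ng/ml EGF stays open, as an untested biological explanation.

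The ESMG array of pig 40 lay between the tissues on the second principal component, at 6.09. Exchanged labels would put ESMG genes on the squamous array of that pig, but 90.7% of 461 genes higher in ESMG on pigs 37 and 39 were higher in its ESMG array (exact 95% interval 87.6% to 93.2%). Overlying mucosa mixed into the gland sample would give 1 mixing share from both gene sets. The median share was 61.6% from the 461 ESMG-higher genes and 44.1% from 111 squamous-higher genes, a difference of -0.17 (interval -0.24 to -0.10) on a scale of fractions. The ESMG arrays of pigs 37 and 39 both helped choose the genes and served as the gland level, and the interval is over genes of a single array. Whether those 2 arrays were free of mucosa was not tested. The squamous genes CRNN and A2ML1 had ESMG means of 12.27 and 12.80, near their squamous means of 12.69 and 13.28. The difference therefore does not decide whether mixing was the only cause. Both shares were above 0, so mixing as part or all of the cause stays open, and so does a difference between animals, which was not tested.

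Other splits of the arrays were tested beside each count. For the genes called, 1 of 10 splits of 6 arrays, the real one, gave as many in each comparison (374, 2065 and 2035, with 0 in the highest other split of each), and 10 splits are too few for a share under 0.05. Among the 4 splits of the tissue arrays that part all 3 pigs, the highest other count was also 0; the others mix ESMG and squamous arrays. For the lists called, 3, 3 and 2 of 10 splits gave as many, with 9, 11 and 12 lists in the real splits and up to 12, 13 and 12 in another, and these splits too are too few for a share under 0.05. For genes on which spheroids differ from both tissues, 2 of 100 splits of the 9 arrays, the real one among them, gave as many as the real 1490. The tissue arrays share animals, which this count ignores, and splits of whole animals are too few for a share under 0.05. Both of those 2 splits keep the spheroid arrays together, the other one with 1595 genes, and the highest count of the 98 splits that do not was 173. The share of 2 in 100 therefore counts how often the draw kept those arrays together, and it does not exclude chance.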

How the results depend on the processing

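Leaving out both tissue arrays of pig 40 was chosen only after seeing the data; the other alternatives were planned. No called result reversed. Of 107 called results on named genes, 103 kept call and direction in every setting run for them, and 27 of 32 list calls were kept under every setting except the estimated correlation, under which 0 lists were called. Another 13 lists, counted per comparison, gained a call in some setting, 8 without a single array and 7 under fry. With no fold minimum, 739 genes were called in ESMG versus squamous (537 higher, 202 lower), 5069 in spheroids versus ESMG (2914, 2155), 5002 in spheroids versus squamous (2879, 2123) and 3950 the same way in both spheroid comparisons. Under treat against the fold these were 61 (61, 0), 708 (273, 435), 761 (312, 449) and 503; for the 0, treat's own unadjusted p under 0.05, counted after seeing the data, gave 11. The first drops a criterion, and treat tests each change against the fold in place of against 0. Array weights gave 120 genes lower in ESMG than in squamous tissue. Without both pig 40 tissue arrays, 572 genes were called, 111 of them lower, and 357 were shared with the 374. Leaving out single arrays gave 276 to 569 genes in ESMG versus squamous, 24 to 122 of them lower. The paired fits with pig as a replicate block called 397 genes as a fixed block (365 shared) and 335 as a random block (335 shared), and apart from PYGM, the leukocyte, hypoxia and glandular lists of spheroids versus squamous and the immediate early list of ESMG versus squamous they changed no other call of a named gene or list. The share of squamous-higher genes whose spheroid mean lay nearer squamous was 9.62% after quantile normalization, 8.11% after cyclic loess, 18.2% without the dimmest 1 in 3 genes, 25.7% with no fold minimum, 23.4% without pig 40, 18.2% measured on pig 39 after choosing genes without it, and 4.17% to 20.5% without single arrays. That of ESMG-higher genes was 63.3% after cyclic loess, 52.4% without the dimmest 1 in 3 genes, 51.6% with no fold minimum, 52.6% measured on pig 40 after choosing genes without it, and 57.5% to 62.6% without single arrays. Where construction does not show it, the cause was not tested. Setting array medians equal moved the median log2 change of all genes by 0.11 in spheroids versus ESMG and 0.13 in spheroids versus squamous. Background correction and signal over background could not be varied from RMA values, and their effect on dim genes is unknown.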

Other observations

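The gene families described here were chosen after seeing the data, by symbol, from 22 families. Fibroblast and matrix genes fell in spheroids against ESMG in 16 of 19 (median -3.83, camera adjusted p = 0.0634 with an estimated correlation). Whether the falls of family members below came from fewer cells of other types was not tested. Matrix metalloproteinases split in spheroids against ESMG. Of 13 measured, 7 were higher: MMP13 (57.2-fold), the macrophage elastase MMP12 (15.3-fold), the stromelysin MMP3 (14.9-fold), the matrilysin MMP7 (13.4-fold), the gelatinase MMP9 (5.65-fold), MMP1 (3.41-fold) and MMP19 (2.01-fold). Another 3 were lower: MMP16 (10.6-fold), the gelatinase MMP2 (9.30-fold) and MMP27 (4.98-fold). The counts were 9 and 3 with array medians set equal and 6 and 3 after cyclic loess. The membrane mucins MUC4 (17.7-fold), MUC13 (16.5-fold), MUC1 (6.59-fold) and MUC20 (3.81-fold) were higher, and the gel-forming MUC19 was 60.4-fold lower, with the same counts of 4 and 1 of 6 under the 3 rescalings.

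Genes of MHC class II, which present antigen, fell in spheroids against ESMG in 7 of 8, with SLA-DRA 35.0-fold and SLA-DQA1 30.5-fold lower; the count was 6 under quantile normalization and with array medians set equal. Leukocyte markers fell beside them in 12 of 21 (median -1.07; adjusted p = 0.425 with an estimated correlation). None of 5 class I genes was called by limma (median log2 change 0.08). The stromal chemokine CXCL12 was 30.9-fold and the lymphoid chemokine CCL19 20.6-fold lower, whereas CXCL8 (5.88-fold) and CXCL2 (3.94-fold) were higher. In all, 2 of 8 CXC chemokines were higher and 3 lower, and of 17 CC chemokines 0 were higher by limma and 3 lower, or 5 lower after cyclic loess. Integrins split as well: ITGA3, ITGB4 (6.03-fold), ITGA2 (3.72-fold), ITGB6 (3.67-fold) and ITGB1 (2.08-fold) were higher, and ITGA4 (3.90-fold), ITGA8 (3.02-fold), ITGA5 (2.36-fold) and ITGA11 (2.09-fold) were lower. These counts of 5 and 4 of 14 were 4 and 3 after quantile normalization, 7 and 3 with array medians set equal and 4 and 4 after cyclic loess. The drug-metabolising oxidases FMO1 and FMO2, 2 of 3 measured, were 33.6-fold and 30.9-fold lower.

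In the ESMG array of pig 40, all 12 immediate early genes lay above the mean of the ESMG arrays of pigs 37 and 39, with a median difference of 0.84; the median for the squamous array of pig 40 was 0.26. All 17 squamous differentiation genes and 15 of 16 smooth muscle genes also lay above it, by medians of 0.44 and 0.55, against -0.13 and 0.07 in the squamous array of that pig. Mucous and serous genes had a median difference of -0.48 in its ESMG array and -0.44 in its squamous array. The squamous reference was the mean of pigs 37 and 39. Without the squamous array of pig 37, the median of that list in spheroids against squamous tissue was higher. The -0.44 may therefore reflect the array of pig 37, and a trait of pig 40 in both tissues is not shown. All these differences are values of a single array with no test.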
